A study of Caenorhabditis elegans with 30 samples.

How the data were processed

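Whole worms of 6 genotypes were collected late in the fourth larval stage from populations synchronised by bleaching and grown at 20 °C on OP50 bacteria. The genotypes were wild type (WT), the long-lived mutants daf-2(e1370) and nuo-6(qm200), the H3.3 double mutant with alleles tm2066 of his-72 and ok2289 of his-71, and the triple mutants daf-2;his-72;his-71 and nuo-6;his-72;his-71, with 5 biological replicates each and 30 samples in all. Total RNA was extracted with a column kit, and mRNA libraries were made by standard Illumina protocols. Strandedness and read length are not stated.

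The deposited values are FPKM, fragments per kilobase of transcript per 1e6 mapped fragments, computed by the authors before deposit. The submitters' processing notes name FastQC, STAR, Cufflinks and Cuffdiff without versions, and name no genome build. There are 6 tables, 1 per genotype, each with 1 FPKM value for each of 20484 genes. All 5 samples of a genotype point to the same table, and how the replicates were combined is not stated. Values per replicate and counts were not analysed here. The spread between replicates is therefore unknown, and no test, interval or adjusted p could be computed. For this case it had been laid down before the data were examined that only ratios of the deposited values would be given, and that a ratio of at least 2 with at least 5 FPKM in the higher pool would take the place of a test. The same step fixed the genotype contrasts, the gene lists and most alternatives.

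Sequencing depth is not stated. It was looked for in the steps between low values, since at a fixed depth FPKM times transcript length comes in whole multiples of a unit. Of low values, between 22.57% and 25.64% per pool lay within 0.1 of a whole multiple, beside 21.66% to 23.27% with transcript lengths shuffled among genes, so no depth could be read off. The counting error of a value is accordingly unknown, and ratios against values far under 1 FPKM are imprecise. The summed FPKM per pool was 1304234 in WT, 1227567 in his-72;his-71, 1294986 in daf-2, 935102 in daf-2;his-72;his-71, 1508331 in nuo-6 and 1177981 in nuo-6;his-72;his-71. The 100 genes with the highest values held between 31.58% and 43% of it.

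Values were used as deposited, with no pseudocount and no rescaling between pools. The positions listed in the tables were compared with the WBcel235 annotation. Of the genes, 20179 were found there by WormBase gene ID, all on the same chromosome, and 8975 had an identical start or end. Among the listed genes, 3726 share a listed locus with another gene, and their values are uncertain. A value of exactly 0 can stand for a gene that was not quantified: 36 genes were listed at 0 in some pool and had at least 20 FPKM in another, rps-3 and rpl-32 among them. Genes listed at 0 in a pool were left out of the ratios that use it, and keeping them was an alternative. Transcript lengths were those of the longest annotated transcript. No genome sequence was at hand, so GC content was not examined.

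The contrasts were H3.3 loss (his-72;his-71 against its background) in WT, daf-2 and nuo-6, and the daf-2 and nuo-6 mutations each with and without H3.3. The difference between the 2 effects of a mutation, without H3.3 less with H3.3, was taken per gene. Pools recur: WT and his-72;his-71 stand in 3 contrasts each, and each of the other pools in 2 contrasts. Effects with and without H3.3 share no pool, and neither do the 3 contrasts of H3.3 loss. They were set against each other by the major-axis slope, Pearson's r and Spearman's rho over all genes with at least 5 FPKM in 1 of the 4 pools. Genes are not independent replicates, so no p-value is attached. Shared genes of contrasts stand beside the number that independent lists of the same sizes would share.

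The 33 gene lists were fixed before the data were examined. They cover the mutated genes and other histones, insulin, DAF-16 and stress responses, mitochondrial and other metabolism, ribosomes, and markers of tissue and stage. Of the list members 1688 were matched to the tables, 28 of these through their current symbol, and 15 were not found. For each list the median log2 ratio of its compared members, less the median of all compared genes, was set beside 10000 random lists of the same size drawn from the same 20 bins of mean expression. A list was called where its median fell outside the middle range of 2.5 to 97.5 percent of these. Random lists assume independent genes, and members of a list rise and fall together, so the percentile is a description. In an alternative the random lists were drawn from 5 bins of expression by 5 of transcript length.

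Genes were named by a rule fixed in the same step: his-71, his-72, daf-2 and nuo-6 always; in each contrast the 8 genes with the largest ratio in each direction; and up to 4 called members of each list by size of ratio. Some were left out for length, in order of rank, 1 that the rule selects is not reported here, and none were added except where the text says that they were chosen after their values were seen. Sperm msp genes, replication-dependent histone genes and ribosomal protein genes have near-identical copies, between which reads may be divided arbitrarily.

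The calling steps were tested on simulated data. For each of the 7 contrasts 200 changed genes were placed into the deposited values of its control pool, with noise of SD 0.15 on the log2 scale in both simulated pools. Of genes changed 2.5-fold between 91.5% and 96% were recovered, of genes changed 4-fold between 99% and 100%, and 0 unchanged genes were called. The noise was chosen and not measured, and it was the same at every expression level. These shares follow largely from that choice, so they check the calculation and not the error of the deposited values. The alternatives were other minimum levels and ratios, pseudocounts, scaling of pools, other ways to take the slope, lists without shared members, removal of the length trend by the median of 20 length bins, and omission of stage and germline lists. Their effect is given in the closing part. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.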

Results

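Gene expression was compared in whole Caenorhabditis elegans collected late in the fourth larval stage, from 6 genotypes with 5 biological replicates each. Histone H3.3 is the form of histone H3 that is put into chromatin outside DNA replication, and his-71 and his-72 are its broadly expressed genes in the worm. The study set H3.3 loss, in the double mutant his-72;his-71, beside long-lived mutants. The daf-2 mutant has reduced insulin receptor signalling. The nuo-6 mutant carries a change in a subunit of respiratory chain complex I. Triple mutants joined each of these mutations to the H3.3 loss, and wild type (WT) was the control. H3.3 loss and without H3.3 stand here for the lack of his-71 and his-72 alone, since other H3.3 genes remained.

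The deposited tables hold 1 FPKM value (sequenced fragments scaled to transcript length and to library size) per gene and genotype for 20484 genes, not 1 value per replicate. There is therefore no spread between replicates, no test and no p-value for any difference. Every fold is a ratio of the authors' 2 pooled values, and higher and lower describe those values alone. A gene is counted as higher or lower where the ratio was at least 2 and the higher pool had at least 5 FPKM. Genes listed at 0 in a pool were left out of ratios. Sequencing depth is unknown. The summed FPKM ran from 935102 in daf-2;his-72;his-71 to 1508331 in nuo-6, and between 10410 and 11115 genes reached 5 FPKM in a pool. A ratio against a pool under 0.1 FPKM is imprecise and gives little more than a direction. Values are also uncertain for the 3726 genes that share a listed locus with another gene, among them far-3, sod-3, hsp-70, bli-1, him-3, flp-1, trx-2, gsto-1, spp-20, cpar-1, elo-5, nuo-6, ndfl-4, nduo-6, nduo-3, epg-2, acdh-2, K01A6.8, col-119, col-124 and T22B7.8. Medians of gene lists are log2 ratios less the median of all compared genes in that contrast. Each stands beside its percentile among 10000 random lists of the same size, matched on expression. The percentile describes these pools and is not a test.

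The mutated genes were examined first. his-71 (WBGene00001945, chromosome X, 7981381 to 7982070) had 303 FPKM in WT, 344 in daf-2 and 223 in nuo-6. It had 0.276 FPKM in his-72;his-71, 0.372 in daf-2;his-72;his-71 and 0.337 in nuo-6;his-72;his-71. his-72 (WBGene00001946, chromosome III, 12367475 to 12369050) had 418, 330 and 226 FPKM in WT, daf-2 and nuo-6. Its values were 0.408, 0.293 and 0.321 FPKM in the his-72;his-71 pools of the WT, daf-2 and nuo-6 backgrounds. These positions are from the authors' tables, and 8975 of 20179 genes there have a start or an end identical to the WBcel235 annotation. Transcripts of daf-2 and nuo-6 were present in every pool. daf-2 (WBGene00000898, chromosome III, 2995763 to 3028800) had 13 FPKM in WT, 12.7 in his-72;his-71, 32.2 in daf-2, 21.2 in daf-2;his-72;his-71, 12 in nuo-6 and 16 in nuo-6;his-72;his-71. nuo-6 (WBGene00012166, chromosome I, 7065263 to 7069188) had 395, 368, 434, 213, 634 and 464 FPKM in the same order. Of the other H3.3 family genes, his-69 stayed at or under 0.51 FPKM in every pool. his-70 had 17.7 FPKM in WT, 0.312 in daf-2 and 22.9 in nuo-6, and his-74 had 160, 49.9 and 138. In the his-72;his-71 pools of these backgrounds his-70 had 25.3, 3.36 and 4.98 FPKM and his-74 had 149.7, 202 and 73.9.

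**Figure D1:**
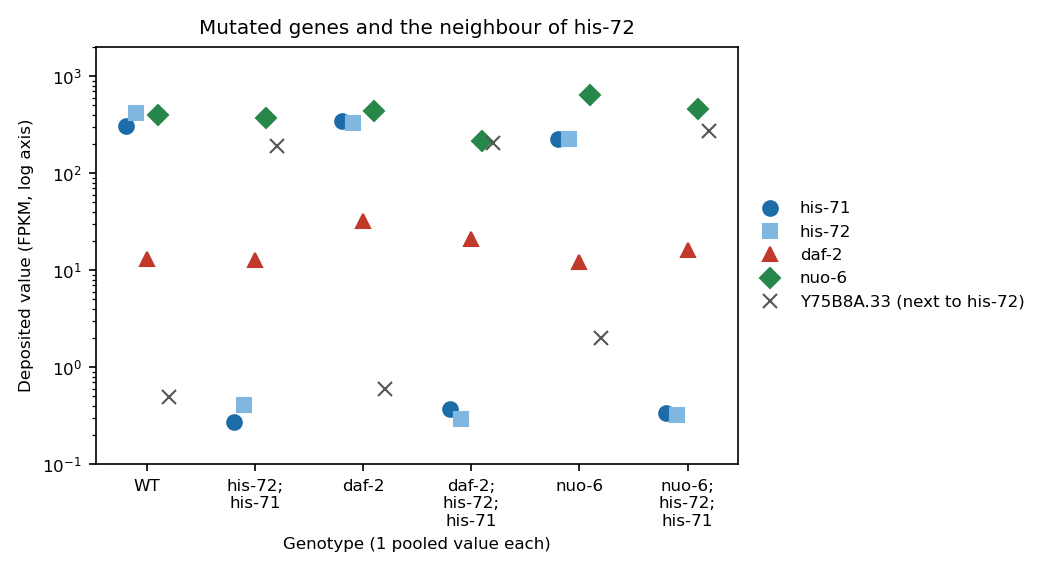
Deposited FPKM (log axis) of the mutated genes and of Y75B8A.33, the gene beside his-72, in the 6 genotypes, 1 pooled value each. his-71 and his-72 lie above 200 FPKM in WT, daf-2 and nuo-6 and under 0.5 FPKM in the other pools, where Y75B8A.33 lies between 193 and 271 FPKM.

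H3.3 loss alone was the smallest of the contrasts. Between his-72;his-71 and WT, 125 genes were higher and 99 lower among 10972 compared. The heat-inducible chaperones were lower: 7 of 21 compared cytosolic heat shock genes were lower and 0 higher. The small heat shock gene hsp-16.41 was 23.9-fold lower (254 FPKM in WT, 10.6 in his-72;his-71), hsp-70 was 20.5-fold lower, hsp-16.2 20.1-fold lower and F44E5.4, of the HSP70 family, 18.4-fold lower. Their list median was -0.54 (percentile 0). These genes are induced by heat and many other stresses, and their levels varied widely across the 6 pools: hsp-16.41 had 1488 FPKM in daf-2, 40.3 in daf-2;his-72;his-71, 160 in nuo-6 and 784 in nuo-6;his-72;his-71.

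Apart from the deleted genes, single uncharacterised genes differed from WT. Y75B8A.33, the gene next to his-72, was 387-fold higher (0.498 FPKM in WT, 193 in his-72;his-71), T22B7.8 was 621-fold higher from a WT value of 0.00927 FPKM, T05B4.9 was 29.5-fold higher and T05B4.8 11-fold higher. F56A4.3 was 285-fold lower and F13G11.3 102-fold lower. Among innate immunity genes 2 of 116 were higher and 1 lower, and the C-type lectin clec-52 was 4.87-fold higher. ER stress genes were 5 of 26 lower, led by abu-1 (2.77-fold) and abu-11 (2.36-fold), which belong to a family of pharynx-associated proteins. Collagens were 7 of 117 lower and 0 higher (median -0.42, percentile 0), with col-124 2.44-fold lower. Of 8 adult onset genes, vit-2 and vit-6, which encode yolk proteins, were lower (2.55-fold and 2.16-fold). Of 60 sperm genes 3 were higher (peel-1 3.82-fold, msd-2 2.33-fold), with a list median of 0.53 (percentile 100). Of 12 HIF-1 response genes 3 were lower, and 4 of 20 DAF-16-induced genes were lower, hsp-16.41 and hsp-16.2 among them. No compared member of the lists of other histones and H3 chaperones, of complex I, of complexes II to V, of germline, cell cycle, muscle, neuron, intestine or heterochronic genes reached a ratio of 2. The split of 125 higher and 99 lower became 90 and 128 with pools scaled to equal median ratios, 38 and 64 with a minimum of 20 FPKM and 21 and 35 with a ratio of 3, so which direction prevailed depended on these settings.

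Reduced insulin signalling with H3.3 present was followed in daf-2 against WT, where 1725 genes were higher and 1506 lower among 11405. The direction that prevailed depended on scaling, with 1612 higher and 1639 lower when pools were scaled to equal median ratios. Genes that the transcription factor DAF-16 is known to induce when insulin signalling is low were higher in 23 of 27 cases and lower in 0 (median 2.54, percentile 100). scl-20 was 1073-fold higher from a WT value of 0.0112 FPKM, the fatty acid binding protein gene far-3 437-fold, the metallothionein mtl-1 240-fold (2.87 FPKM in WT, 689 in daf-2) and cyp-35B1 91.6-fold. The manganese superoxide dismutase sod-3 was 56.3-fold higher (2.95 and 166 FPKM). Detoxification genes were also higher, 42 of 86 cytochrome P450 and UDP-glycosyltransferase genes (6 lower) and 14 of 28 glutathione and SKN-1 response genes, with gst-10 15.8-fold and gst-4 9.10-fold higher. Insulin-like peptides and pathway genes were higher in 23 of 37 and lower in 1 (ins-16 674-fold, ins-35 56.7-fold), and so was daf-2 itself, 2.47-fold.

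Innate immunity genes were 56 of 133 higher and 18 lower, the C-type lectins clec-18 (5519-fold, from 0.00638 FPKM in WT) and clec-128 (2610-fold) among the higher ones. F35E8.7 went from 0.0108 FPKM in WT to 61.5. Among neuron genes, 28 of 57 were higher and 0 lower (median 0.98, percentile 100), with the neuropeptide genes flp-14 and flp-1 3.21-fold and 3.12-fold higher. Heat shock genes were higher in 9 of 21 (sip-1 7.70-fold), HIF-1 response genes in 4 of 13 (sqrd-1 8.49-fold), and the mitochondrially encoded ndfl-4, nduo-6 and nduo-3 were 11.2-fold, 5.60-fold and 2.83-fold higher. Fatty acid metabolism genes went both ways, 14 of 62 higher (lipl-1, 62.3-fold) and 5 lower (acdh-8, 154-fold, and elo-7, 151-fold). In the glyoxylate and trehalose list 2 of 8 were higher, with tps-1, a trehalose synthase gene, at 3.8-fold. In the glycolysis and gluconeogenesis list 2 of 22 were higher, among them pck-1 (2.5-fold), and gpd-4 was 2.90-fold lower.

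Genes of reproduction were lower in the daf-2 pool. Of 54 sperm genes 51 were lower (median -6.46), of 45 germline and meiosis genes 41 (median -1.83), of 20 oocyte genes 14 with 1 higher (median -1.64) and of 36 cell cycle genes 25 (median -1.18), all at percentile 0. The meiotic chromosome axis gene him-3 had 42.8 FPKM in WT and 3.72 in daf-2, 11.5-fold lower. The sperm gene msd-2 was 688-fold lower, the B-type cyclin cyb-1 4.61-fold and the eggshell genes perm-4 and perm-2 21.1-fold and 11.8-fold. msp genes encode nearly identical sperm proteins, and their single values are uncertain. All 8 compared adult onset genes were lower (median -3.18), including the cuticle collagen bli-1 (689-fold, 90.6 and 0.131 FPKM). Collagens were 79 of 128 lower and 21 higher, and col-36 was 1601-fold higher. Other histones and H3 chaperones were 9 of 16 lower and 1 higher, the linker histone hil-1 (54.5-fold). Ribosomal protein medians were lower, -0.38 for cytosolic and -0.60 for mitochondrial ones, with 2 of 79 and 1 of 66 genes past 2-fold. Complex I and body wall and pharyngeal muscle medians were 0.04 and -0.10. DAF-16-repressed genes, defined by lower levels when insulin signalling is low, went both ways with 4 of 12 higher (T24B8.5 21.4-fold) and 5 lower (dod-22 11.7-fold). Their median of -0.49 turned to 0.73 with a minimum of 20 FPKM.

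**Figure D2:**
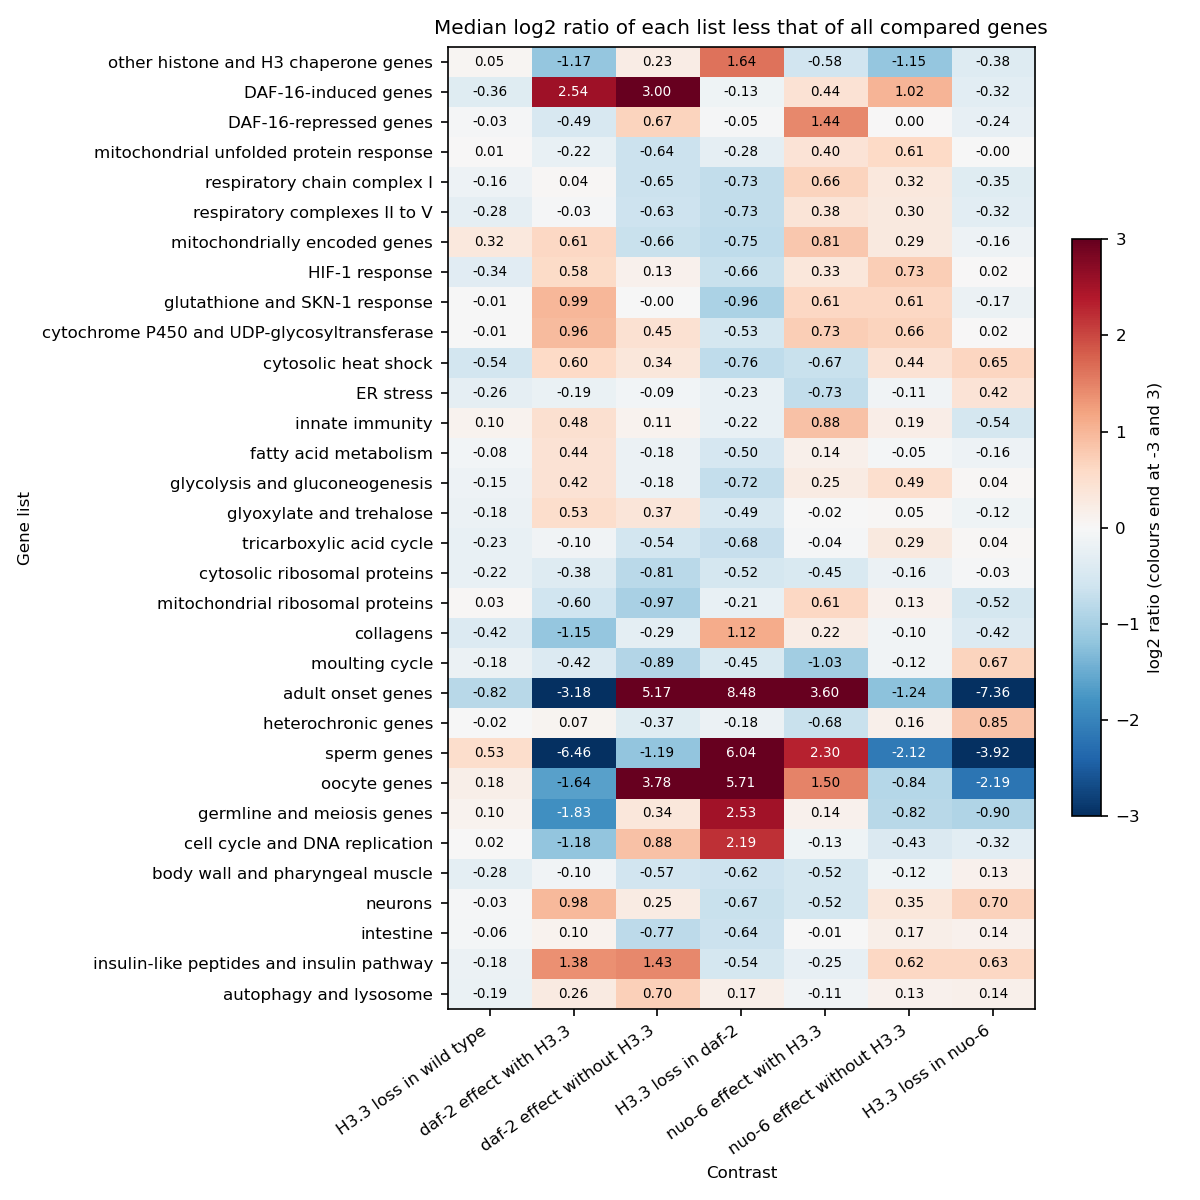
Median log2 ratio of each fixed gene list (rows, the list of mutated and H3.3 genes left out) in 7 contrasts between pools (columns), less the median of all genes compared in that contrast. DAF-16-induced genes have 2.54 and 3.0 for daf-2 with and without H3.3, and the oocyte, sperm and adult onset rows change sign between columns.

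The same daf-2 mutation without H3.3, daf-2;his-72;his-71 against his-72;his-71, gave 1563 higher and 1604 lower genes among 11871 (1643 and 1457 with scaled pools). DAF-16-induced genes were again higher, 24 of 28 and 0 lower (median 3.0, percentile 100). scl-20 was 902-fold, mtl-1 377-fold (1.21 and 457 FPKM), far-3 112-fold and cyp-35B1 71.7-fold higher, and sod-3 was 27.9-fold higher. Insulin-like peptide and pathway genes were higher in 20 of 38 and lower in 1. Neuron genes were higher in 1 of 53 and lower in 1. Glutathione and SKN-1 response genes were higher in 6 of 25 and lower in 1, with gst-41 6.13-fold and gst-10 4.52-fold, and autophagy and lysosome genes in 7 of 31 (median 0.70, percentile 100), led by epg-2 (2.96-fold) and atg-2 (2.78-fold). Cytochrome P450 and UDP-glycosyltransferase genes were 28 of 84 higher and 15 lower, and innate immunity genes 42 of 144 higher and 31 lower. Heat shock genes were higher in 6 of 19 and lower in 0. Oocyte genes were higher in 31 of 33 (median 3.78), led by meg-1 (147-fold) and the eggshell gene perm-2 (133-fold, 8.68 and 1157 FPKM), whereas sperm genes were lower in 40 of 61 and higher in 1 (median -1.19). Yolk protein genes were far higher, vit-5 1289-fold (0.951 and 1225 FPKM) and vit-2 404-fold, and in the adult onset list 7 of 11 were higher and 4 lower. Collagens were 62 of 154 higher, led by col-183 (3550-fold), and 56 lower. Mitochondrial ribosomal proteins were lower in 37 of 66 (median -0.97, percentile 0), cytosolic ones in 12 of 80 (median -0.81), intestine genes in 14 of 30 with 2 higher (cpr-5 6.23-fold and pept-1 5.74-fold lower), moulting cycle genes in 11 of 29 with 1 higher, and C36C5.15 was 789-fold lower.

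Across the 12241 genes with at least 5 FPKM in 1 of the 4 pools, the daf-2 effects with and without H3.3 had a major-axis slope of 0.94, with Pearson's r of 0.44 and Spearman's rho of 0.39 across genes, which are not independent replicates. The 2 effects share no pool. Ordinary least squares gave a slope of 0.427. The SD of the log2 ratios was 1.73 with and 1.68 without H3.3. A major axis lies near 1 where the spreads are alike and r is above 0. The slope of 0.94 thus does not show that single genes kept their effect. Of the genes compared in both, 609 were higher in both backgrounds, where 142 would be shared by independent lists of these sizes, and 588 were lower in both (188 for independent lists). A further 177 genes were lower with H3.3 and higher without it (144), and 16 the reverse (185).

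H3.3 loss in the daf-2 background, daf-2;his-72;his-71 against daf-2, left 1991 genes higher and 1435 lower among 11663, against 125 and 99 in the WT background. The direction that prevailed turned with a ratio of 1.5 (2951 higher, 3531 lower) and with a minimum of 25 FPKM (883 and 901), and with a ratio of 3 it was more marked (1304 and 310). Among genes with at least 20 FPKM in both pools the median log2 ratio was -0.32, so abundant transcripts sat lower in the triple mutant pool. Reproductive and adult genes made up the largest list differences. Oocyte genes were higher in 31 of 33 (median 5.71), sperm genes in 43 of 46 (6.04), germline and meiosis genes in 42 of 46 (2.53), cell cycle genes in 32 of 36 (2.19) and adult onset genes in 9 of 11 (8.48), with 0 lower in each and all at percentile 100. perm-4 had 0.413 FPKM in daf-2 and 557 in the triple mutant, 1348-fold higher, vit-3 and vit-5 were 1555-fold and 1549-fold higher, the germ cell translational regulator gld-1 was 18.6-fold higher (10.4 and 193 FPKM) and the B-type cyclin cyb-2.2 38.5-fold. The neuropeptide gene nlp-39 went from 0.0127 FPKM to 45.5. Collagens were higher in 75 of 151 and lower in 16.

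Of the other histone and H3 chaperone genes 12 of 17 were higher and 0 lower, among them hil-7 (20.6-fold), cpar-1, a centromeric H3 variant gene (15.9-fold), and the germline H3 chaperone asfl-1 (8.88-fold). This rise was not shared by the other backgrounds. The median gene of this list had 14.3 FPKM in daf-2 and 43.6 in daf-2;his-72;his-71. It had 17.75 in WT and 19.9 in his-72;his-71, and 19.6 in nuo-6 and 11.8 in nuo-6;his-72;his-71. The H3.3 gene his-74, still present, was 4.04-fold higher in the triple mutant than in daf-2. Its value there, 202 FPKM, compares with 160 in WT. Lower genes included 15 of 28 glutathione and SKN-1 response genes (gst-12 4.89-fold, gst-20 4.68-fold), 10 of 21 heat shock genes with 2 higher (F44E5.4 37.1-fold, hsp-16.41 36.9-fold lower), 13 of 57 neuron genes, 15 of 59 fatty acid genes with 2 higher (elo-5 6.32-fold lower), 8 of 22 glycolysis and gluconeogenesis genes with 3 higher, 4 of 13 HIF-1 response genes and 5 of 12 mitochondrially encoded genes. Lower values were not confined to these lists. Median FPKM in daf-2 and the triple mutant was 282 and 134 for muscle, 98.2 and 43.2 for intestine and 222 and 116 for tricarboxylic acid cycle genes. ER stress (67 and 70.1) and autophagy and lysosome genes (33.3 and 36) were among those that did not fall. F56A4.3 went from 433 FPKM in daf-2 to 0.0129. DAF-16-induced genes had a median of -0.13 (percentile 78.3), with 4 of 28 higher and 5 lower.

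Taken gene by gene, the daf-2 ratio without H3.3 was at least 2-fold higher than that with H3.3 for 2170 genes and at least 2-fold lower for 1840, among 12241 (3093 and 3730 with a ratio of 1.5, 1501 and 486 with a ratio of 3). A higher ratio can also be a smaller fall, as in sperm genes (medians -6.46 with and -1.19 without H3.3). In the first group were 9 of 11 adult onset genes (median 9.15), 31 of 33 oocyte genes (median 5.56), 53 of 59 sperm genes (median 5.31, 1 in the second group), 42 of 46 germline genes and 32 of 36 cell cycle genes. In the second group were 16 of 28 glutathione and SKN-1 response genes (gst-12, 5.20-fold), 18 of 57 neuron genes, 10 of 12 mitochondrially encoded genes (ndfl-4, 12.7-fold) and 34 of 92 cytochrome P450 and UDP-glycosyltransferase genes, with another 10 of the 92 in the first group. Among genes with at least 20 FPKM in every pool used, the median log2 difference was -0.31, so abundant transcripts in general leaned towards the second group. For DAF-16-induced genes the median of this difference was -0.07 (percentile 81.1).

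**Figure D3:**
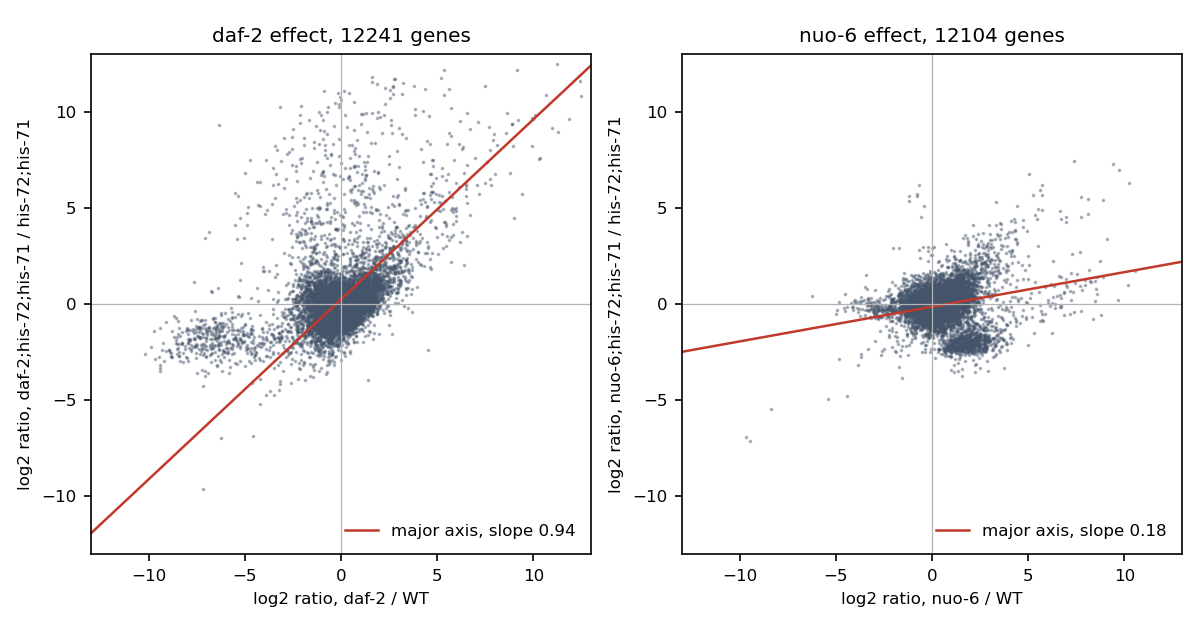
log2 ratio of each gene for the daf-2 mutation (left, 12241 genes) and the nuo-6 mutation (right, 12104 genes), with H3.3 on the horizontal axis and without it on the vertical axis, 1 point per gene. The red line is the major axis, with a slope of 0.94 for daf-2 and 0.18 for nuo-6.

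The nuo-6 mutation with H3.3 present, nuo-6 against WT, gave 2416 higher and 641 lower genes among 11716. Transcript length mattered in this contrast. The log2 ratio had a Spearman's rho of -0.35 with length across genes, beside -0.00 for his-72;his-71 against WT and -0.11 for nuo-6;his-72;his-71 against his-72;his-71. With the length trend removed, an alternative chosen after the data were seen, 2007 genes were higher and 898 lower. Ratios also scattered more from gene to gene. Across 78 cytosolic ribosomal protein genes with at least 100 FPKM in every pool, the SD of log2 ratios was 0.51 here. It was 0.50 for H3.3 loss in nuo-6 and between 0.12 and 0.26 in the contrasts of 2 pools without the nuo-6 pool. The cause of this wider spread was not tested. Lists of mitochondrial function differed among themselves. Of 35 complex I genes 9 were higher and 0 lower (median 0.66, percentile 100), including C33A12.1 (3.34-fold, 314 and 1048 FPKM) and lpd-5 (2.85-fold). Mitochondrial ribosomal proteins were higher in 21 of 66 (median 0.61, percentile 100), led by mrps-33 (4.45-fold) and mrps-14 (4.12-fold), whereas the median of cytosolic ones was -0.45. Among random lists matched on length as well, the complex I and mitochondrial ribosomal percentiles were 99.7 and 100. Mitochondrially encoded genes were higher in 6 of 12 (percentile 99.5, and 98.7 with length matching). Complexes II to V were higher in 6 of 35 (98.8, and 96.3 with length matching, inside the middle range), and the mitochondrial unfolded protein response in 4 of 17 with 1 lower (95.6, inside that range, and 99.6 with length matching; sod-3 6.91-fold, thioredoxin trx-2 4.08-fold). No tricarboxylic acid cycle gene of 26 reached a ratio of 2, and their median was -0.04.

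Detoxification and immunity genes were higher too, 36 of 85 cytochrome P450 and UDP-glycosyltransferase genes (2 lower), 13 of 28 glutathione and SKN-1 response genes (gsto-1 6.40-fold, gst-19 6.32-fold) and 65 of 131 innate immunity genes with 12 lower (the antimicrobial spp-20, 217-fold higher). Heat shock genes were lower in 4 of 21 and higher in 1 (median -0.67, percentile 0). The metallothionein mtl-2 was 24.2-fold higher. DAF-16-induced genes were 11 of 24 higher and 3 lower (far-3 15-fold, mtl-1 11.9-fold), with a median of 0.44 (percentile 98.8, and 97.3 with length matching, inside the middle range). Adult onset genes were higher in 8 of 11 (median 3.60), among them col-19, the collagen of the adult cuticle (168-fold, 7.10 and 1194 FPKM), and vit-5 (48.6-fold). Sperm genes were higher in 64 of 73 and lower in 1 (median 2.3, and 1.52 with the length trend removed) and oocyte genes in 19 of 27 (median 1.5; perm-2, 17.5-fold). Moulting cycle genes were lower in 12 of 28 (nhr-25 3.64-fold), muscle genes in 8 of 30 with 1 higher (tnt-4 4.77-fold and myo-2 4.21-fold lower) and ER stress genes in 7 of 26, led by abu-6 (30.7-fold) and abu-10 (23.1-fold). The desaturase fat-7 was 13.1-fold lower and ZK218.5 827-fold lower (34.8 and 0.0421 FPKM).

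**Figure D4:**
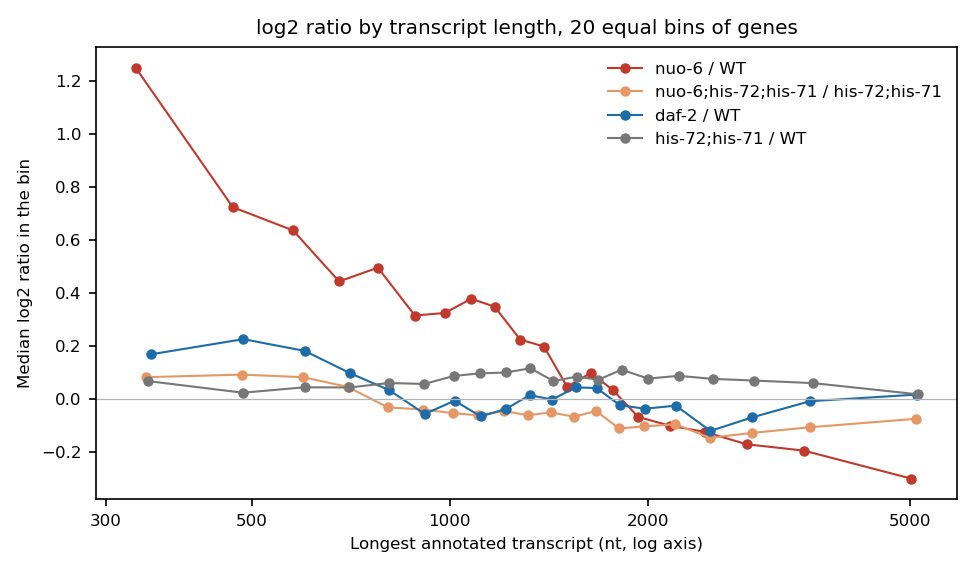
Median log2 ratio in 20 equal bins of genes by the length of the longest annotated transcript (log axis, nt) for 4 contrasts, 1 line each. nuo-6 against WT runs from 1.25 in the bin of shortest transcripts to -0.30 in that of the longest, and the bins of the other 3 contrasts lie between -0.14 and 0.23.

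Without H3.3 fewer genes passed in the nuo-6 contrast. nuo-6;his-72;his-71 against his-72;his-71 had 655 higher and 765 lower genes among 11374, but 336 and 215 with a minimum of 20 FPKM. Complex I genes were 0 of 35 higher and 1 lower, with a median of 0.32 (percentile 100), and mitochondrial ribosomal proteins had a median of 0.13 (percentile 94.8) with none past 2-fold. The mitochondrial unfolded protein response was higher in 2 of 17 and lower in 0, with a median of 0.61 (percentile 100), beside 0.40 in the other background. Detoxification genes were higher as in the other background, glutathione and SKN-1 response in 10 of 27 (gst-14 12.4-fold, gst-12 6.85-fold) and cytochrome P450 and UDP-glycosyltransferase in 26 of 77. Innate immunity genes were 16 of 124 higher and 20 lower. HIF-1 response genes were higher in 6 of 13 (gst-19 6.41-fold, F22B5.4 5.14-fold) and DAF-16-induced genes in 10 of 21 (far-3 13-fold, mtl-1 8.38-fold). Heat shock genes were higher in 8 of 20, hsp-16.41 73.8-fold and hsp-16.2 53-fold. hsp-16.41 and hsp-16.2 had their lowest values of the 6 pools in his-72;his-71, the denominator here. Sperm genes were lower in 56 of 60 (median -2.12), oocyte genes in 10 of 22, germline genes in 15 of 46, adult onset genes in 4 of 6 and other histones in 10 of 16. ZK218.11 and ZK218.5 were 141-fold and 121-fold lower. Of 60 fatty acid genes 6 were lower (acdh-2 9.52-fold, fat-7 6.79-fold) and 1 higher.

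The nuo-6 effects with and without H3.3 had a major-axis slope of 0.18 over 12104 genes, with r of 0.14 and rho of 0.11 across genes. The slope was 0.29 over genes called in either background and 0.095 by ordinary least squares. The SD of the log2 ratios was 1.23 with and 0.86 without H3.3. The wide gene-to-gene scatter of the nuo-6 pool enters the first of these. A smaller nuo-6 effect without H3.3 is therefore not separated from scatter in that pool. Genes higher in both numbered 397, where 94.2 would be shared by independent lists, and 46 were lower in both (41.7). A group of 379 genes was higher with H3.3 and lower without it (122 for independent lists), and 13 were the reverse (32.2).

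H3.3 loss in the nuo-6 background, nuo-6;his-72;his-71 against nuo-6, had 824 higher and 2014 lower genes among 11900. The reproductive and adult lists lay on the opposite side of 0 from those of H3.3 loss in daf-2. Sperm genes were lower in 69 of 73 (median -3.92), oocyte genes in 23 of 27 (-2.19), germline genes in 23 of 46 (-0.90) and adult onset genes in 9 of 11 (-7.36). col-19 was 344-fold lower, vit-6 301-fold (615 and 2.04 FPKM), ssp-37 186-fold and perm-4 28.9-fold. Collagens were 50 of 128 lower (col-119 530-fold) and 11 higher, and innate immunity genes 43 of 133 lower and 10 higher. Complex I genes were lower in 6 of 35 and mitochondrial ribosomal proteins in 14 of 66 (median -0.52, percentile 0), and the length trend of the nuo-6 pool enters this contrast as well (rho 0.28). Higher were 16 of 55 neuron genes (flp-32, 4.88-fold), 9 of 33 insulin-like peptide and pathway genes with 2 lower, 6 of 26 ER stress genes (abu-10, 15-fold), 6 of 20 heat shock genes with 1 lower, 4 of 28 moulting cycle genes (nhr-25, 4.51-fold) and 3 of 12 heterochronic genes (lin-46, 2.71-fold). Y75B8A.33 was 137-fold higher. Gene by gene, the nuo-6 ratio without H3.3 was at least 2-fold higher than that with H3.3 for 870 genes, led by hsp-16.41 (117-fold) and hsp-70 (112-fold). It was at least 2-fold lower for 2332.

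**Figure D5:**
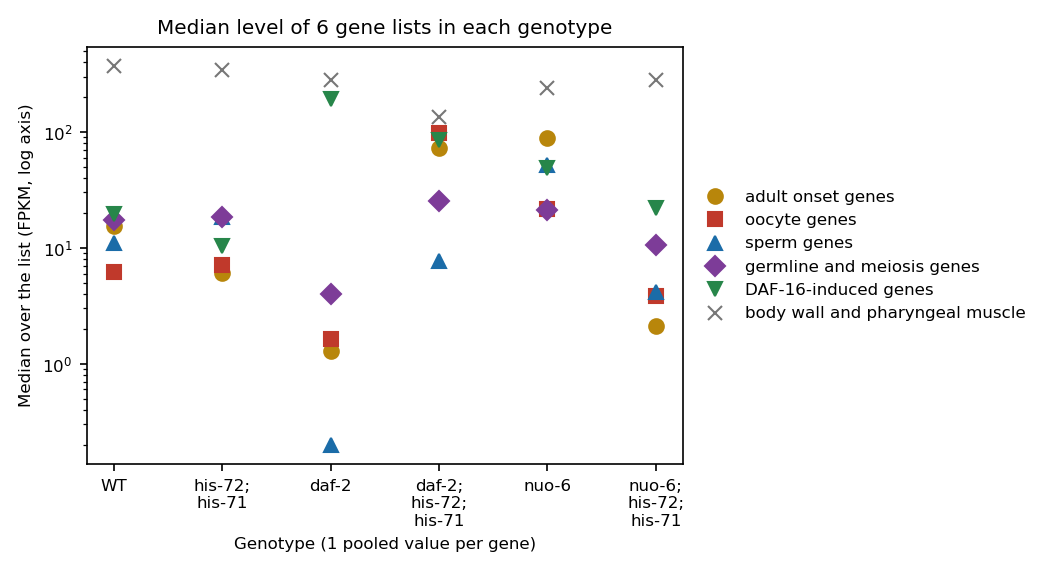
Median FPKM (log axis) of 6 gene lists in each genotype, over the members that reach 5 FPKM in some pool. Adult onset genes have medians of 72 and 88.9 FPKM in daf-2;his-72;his-71 and nuo-6, and between 1.29 and 15.4 in the other 4 genotypes.

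The reproductive and adult lists differed between the 6 pools, though not all alike. The median adult onset gene had 15.4 FPKM in WT, 6.02 in his-72;his-71, 1.29 in daf-2, 72 in daf-2;his-72;his-71, 88.9 in nuo-6 and 2.11 in nuo-6;his-72;his-71. The median oocyte gene had 6.18, 7.11, 1.64, 98.2, 21.8 and 3.88 FPKM in that order, and the median sperm gene 11, 18.5, 0.198, 7.72, 51.9 and 4.13, so that sperm genes were lower in daf-2;his-72;his-71 than in WT where oocyte and adult onset genes were higher. These values stand beside every contrast above that uses the daf-2, daf-2;his-72;his-71, nuo-6 or nuo-6;his-72;his-71 pool. In nuo-6;his-72;his-71 against his-72;his-71 the sperm, adult onset and oocyte medians were -2.12, -1.24 and -0.84. Genes outside these lists can follow the same stages.

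The daf-2 and nuo-6 mutants were compared because both are long-lived. Of 10759 genes compared in both contrasts against WT, 453 were higher in both and 200 lower in both, where 191 and 89.7 would be shared by independent lists of these sizes. Opposed directions occurred as well: 369 genes were lower in daf-2 and higher in nuo-6 (226), and 59 were the reverse (75.5). Both contrasts use the WT pool, so part of the excess may come from that shared control, and 1 pooled value per genotype allows neither a split of WT nor a simulation of its error. daf-2 with H3.3 and nuo-6 without it share no pool. They had 320 genes higher in both (61.7 for independent lists) and 483 lower in both (76.6), with 22 lower in daf-2 and higher in nuo-6 (69.3) and 16 the reverse (68.2). Sperm (-6.46 and -2.12), germline (-1.83 and -0.82), oocyte (-1.64 and -0.84) and adult onset medians (-3.18 and -1.24) were below 0 in both of these contrasts. A likeness in stage or germ line content is therefore not separated from this overlap. The other comparison with no shared pool, daf-2 without H3.3 and nuo-6 with it, had 465 higher in both (174), 130 lower in both (88.2), 504 lower in daf-2 and higher in nuo-6 (263) and 35 the reverse (58.5). Without H3.3, where the his-72;his-71 pool is shared, 216 genes were higher in both triple mutants (39.1) and 499 lower in both (111).

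The 3 H3.3-loss contrasts share no pool and had few genes in common. Among 10228 genes compared in all 3, 7 were higher in each, where independence would give 0.596, and 5 were lower in each (1.08), his-71 and his-72 included. Genes in this group were singled out after their values were seen. The higher ones were Y75B8A.33, T20D4.12, T20D4.10, W08E12.2, phat-5, K01A6.8 and H37A05.4. Of these, T20D4.12 and T20D4.10 lie close together on chromosome V (3397065 to 3397789 and 3400255 to 3401045). Y75B8A.33 lies beside the deleted his-72. The comparison with independence does not allow for such neighbours. T20D4.12 was 7.0-fold, 4.26-fold and 3.8-fold higher in the WT, daf-2 and nuo-6 backgrounds and W08E12.2 6.85-fold, 3.60-fold and 9.20-fold. Besides the deleted genes, nspc-19, nspc-1 and nspc-17, close copies of one another, were lower, with nspc-19 4.81-fold, 4.34-fold and 3.22-fold lower. Between the daf-2 and nuo-6 backgrounds, 638 genes were higher on H3.3 loss in daf-2 and lower on H3.3 loss in nuo-6 (185 for independent lists), where 71 were higher in both (113) 159 were the reverse (90.3) and the number lower in both was 0.705 times that of independent lists (148).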

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

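All tests in this part were chosen after the result was seen. A result was taken up here where the median of a gene list lay on opposite sides of 0 under a contrast in 2 backgrounds, with both medians at least 1 in size and outside the middle range of random lists; smaller opposed medians, such as those of germline, cell cycle and neuron genes, are not listed. Because each genotype has 1 pooled value these differences were not tested. In adult onset genes the daf-2 medians with and without H3.3 were -3.18 (8 genes) and 5.17 (11 genes), a difference of 8.35. Adult onset medians for nuo-6 were 3.60 (11 genes) with and -1.24 (6 genes) without H3.3, a difference of -4.84. For H3.3 loss in daf-2 and in nuo-6 the adult onset medians were 8.48 and -7.36, a difference of -15.84. Sperm medians for nuo-6 were 2.3 (73 genes) with and -2.12 (60 genes) without H3.3, a difference of -4.42. Those for H3.3 loss in daf-2 and in nuo-6 were 6.04 (46 genes) and -3.92 (73 genes), a difference of -9.96. Oocyte medians for daf-2 were -1.64 (20 genes) with and 3.78 (33 genes) without H3.3, a difference of 5.42. For H3.3 loss in daf-2 and in nuo-6 the oocyte medians were 5.71 and -2.19, a difference of -7.90. The genes compared are not the same in each pair, since a gene had to reach 5 FPKM in 1 of the pools of its contrast.

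The first pattern weighed was that reproductive and adult genes moved oppositely between backgrounds. A transcript-length bias between pools is argued against as its whole cause, because the smallest of the opposed medians of H3.3 loss in daf-2 and nuo-6 was still 2.27 in size after the length trend was removed, and those of the daf-2 and nuo-6 effects above stayed at or beyond 1.52 or -1.21. A hypothesis that stays open is that the pools were collected at different developmental stages: the adult onset and oocyte medians, from skin and gut and from the germ line, were on the same side in 6 of the 6 contrasts with an oocyte median of at least 0.5 in size, which share pools and so are not independent, while H3.3 loss in WT had -0.82 and 0.18. An action of H3.3 on the pace of development that depends on the background, and chance differences in the time of collection, are not separated by these values and were not tested.

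The second pattern was that short transcripts were higher in the nuo-6 pool. Length bias as the whole cause of the complex I and mitochondrial ribosomal medians was examined with random lists matched on length and expression, where the lower of the percentiles was 99.73. That matching used 5 bins of length. Among the shortest transcripts the median log2 ratio fell from 1.25 at 333 nt to 0.45 at 679 nt, within 1 such bin. Part of the trend thus remained inside a bin, and these percentiles do not decide the question. A length-dependent bias of the nuo-6 pool stays open as a hypothesis: within the 66 mitochondrial ribosomal proteins rho was -0.39 for nuo-6 against WT, beside values between -0.18 and 0.24 in the contrasts without that pool, but in cytosolic ribosomal proteins it was -0.30 for nuo-6 and -0.33 for daf-2 against WT. An adult stage of the nuo-6 pool cannot be told apart from such a bias: daf-2;his-72;his-71 against WT, where adult onset and oocyte genes were also higher, had a Spearman's rho of log2 ratio and length of -0.045 over 10231 genes outside the lists (nuo-6 -0.36), but its sperm median against WT was -0.66 where that of nuo-6 was 2.3, so the stages do not match. RNA quality was not analysed here, and a response of short mRNAs to the nuo-6 mutation was not tested.

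The third pattern was that Y75B8A.33 had 193, 205 and 271 FPKM in the pools that lack his-71 and his-72 and between 0.498 and 1.99 in the others. Transcription running on from the his-72 promoter is a candidate explanation: Y75B8A.33 starts 101 bases downstream of his-72 on the same strand, and among expressed genes within 25000 bases it alone of 8 was at least 2-fold higher in all 3 contrasts, where near his-71 this held for 0 of 5. A derepression of Y75B8A.33 by the loss of H3.3 protein cannot be told apart from it, because 0 of the 3 pools that lack his-71 transcripts keep those of his-72; that loss is also partial, since the H3.3 gene his-74 had 149.7, 202 and 73.9 FPKM in them.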

How the results depend on the processing

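The alternatives that removed the length trend, kept genes listed at 0, left out the stage and germline lists, matched random lists on length or set daf-2 beside nuo-6 without a shared pool were chosen after the result was seen. No paired analysis was possible because each genotype has 1 pooled value. For the same reason these alternatives, laid down before the data were examined, were not run: count-based normalization and tests, fits with a replicate block or with fewer genotypes, thresholds on adjusted p, leaving out replicates, dividing the WT samples, set tests (camera, fry), adjustment over a list alone, simulated shared controls and bootstrap intervals. Depth is unknown, which leaves the counting error of every value open and weighs most on ratios against low values. Of 138 alternative values of gene counts and slopes, 80 stayed within 1.5-fold and 58 moved further, the gene counts only with the minimum level or the ratio, by construction. Counts of genes changed follow in this order: H3.3 loss in WT, daf-2 with H3.3, daf-2 without, H3.3 loss in daf-2, nuo-6 with, nuo-6 without, H3.3 loss in nuo-6, the daf-2 and the nuo-6 difference between backgrounds, and genes shared by daf-2 and nuo-6. As reported they were 224, 3231, 3167, 3426, 3057, 1420, 2838, 4010, 3202 and 653. With no filter other than a value above 0, more genes could pass: 1723, 7307, 6707, 7029, 6281, 4500, 6635, 7303, 6625 and 1611. With a minimum of 20 FPKM they were 102, 1631, 1788, 2071, 1725, 551, 1374, 2176, 1654 and 356, and with 25 FPKM 87, 1416, 1594, 1784, 1532, 465, 1201, 1860, 1451 and 311. With a ratio of 1.5 they were 823, 5527, 5718, 6482, 5382, 2901, 5023, 6823, 5633 and 1359, and with a ratio of 3 they were 56, 1611, 1658, 1614, 1589, 751, 1554, 1987, 1767 and 251. A minimum of 1 FPKM moved H3.3 loss in WT to 473, daf-2 with and without H3.3 to 5141 and 4927, nuo-6 without to 2752 and H3.3 loss in nuo-6 to 4476. Leaving out the stage and germline lists removes too few genes to show whether stage underlies the counts. Which direction prevailed changed with some of these. H3.3 loss in WT went from 125 higher and 99 lower to 38 and 64 at 20 FPKM, 32 and 55 at 25 FPKM, 21 and 35 at a ratio of 3, 90 and 128 with pools scaled by median ratios, and 81 and 84 with a pseudocount of 1 FPKM. daf-2 with H3.3 had 2539 and 2602 at 1 FPKM, 795 and 816 at a ratio of 3 and 1612 and 1639 scaled, and nuo-6 without H3.3 had 336 and 215 at 20 FPKM and 286 and 179 at 25 FPKM. daf-2 without H3.3 had more higher genes (3434 and 3273 with no filter, 910 and 878, 802 and 792 at 20 and 25 FPKM, 1026 and 632 at a ratio of 3, 1643 and 1457 scaled, 1450 and 1439 with a pseudocount of 1 FPKM). H3.3 loss in daf-2 had 883 and 901 at 25 FPKM and 2951 and 3531 at a ratio of 1.5, and the daf-2 difference 927 and 933, and 3093 and 3730. The cause was not tested. The daf-2 slope was 0.427 by ordinary least squares, and the nuo-6 slope was 0.29 over genes called in either background and 0.095 by ordinary least squares; least squares takes a lower slope by construction where r is low. Of 2668 alternative list medians 375 moved, and 11 changed sign in lists that were called in that contrast. Sign changes of lists that were not called are counted among those that moved. The cause was not tested. DAF-16-repressed genes changed to 0.86 (25 FPKM) and 0.73 (20 FPKM) for daf-2 with H3.3, to -0.64 without shared members for daf-2 without H3.3, and to -0.030 (20 FPKM) and -0.067 (without shared members) for their difference. For daf-2 without H3.3, heat shock genes changed to -0.053 without shared members and innate immunity genes to -0.15 with no filter and -0.0019 at 1 FPKM. For H3.3 loss in WT, mitochondrial ribosomal proteins changed to -0.014 with no filter and -0.0034 at 1 FPKM, and insulin-like peptide and pathway genes to 0.018 at 25 FPKM. Of 7233 alternative values of named genes 451 moved: 272 with a pseudocount of 1 FPKM, 133 with 0.1 FPKM and 46 with the length trend removed. Where the reported ratio was at least 2 in either direction, 0 changed sign. Sign changes of smaller ratios were not counted separately.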

Other observations

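All gene families and genes in this part were chosen after their values were seen, and the values stand without a test. Families with shared name stems, outside the fixed lists, differed to unequal extents from random lists matched on expression. In daf-2 against WT 7 of 9 scl genes, which encode secreted SCP/TAPS proteins, were higher (median 4.57), and without H3.3 8 of 10 with 1 lower (median 5.30). Neuropeptide-like nlp genes were higher in 18 of 33 and lower in 0 (median 1.06), transthyretin-related ttr genes in 24 of 45 with 3 lower (median 1.02), neuropeptide receptor npr genes in 7 of 10 and potassium channel twk genes in 9 of 22. The percentiles were 100 for scl, nlp and ttr, but 83.8 for npr and 95.6 for twk, which lie inside the middle range of random lists. Families were taken up because a large share of their members was called in 1 direction in the same contrast. Percentiles far from the middle follow in part from that choice. In nuo-6 against WT 34 of 58 fbxa genes, which encode F-box proteins, were higher and 0 lower (median 0.97), and without H3.3 25 of 61 were higher and 2 lower (median 0.82). The astacin protease genes nas were lower in 11 of 14 and higher in 1 for nuo-6 against WT (median -1.47), and for H3.3 loss in nuo-6 10 of 16 were higher and 1 lower.

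The nspc genes, small secreted peptide genes, were lower on H3.3 loss in each background: 8 of 13 in WT (median -1.83), 8 of 13 in daf-2 (median -1.44) and 7 of 13 in nuo-6 (median -1.09), with 0 higher. These genes are close copies of one another, so their values are not independent. In H3.3 loss in daf-2, 14 of 22 bath genes (2 lower), 10 of 18 skr genes (Skp1-related), 8 of 10 fbxc genes and 8 of 10 cec genes (chromodomain proteins) were higher, whereas 10 of 25 bath genes were lower on H3.3 loss in nuo-6. The related nspb genes were lower in 9 of 10 for daf-2 against WT and in 7 of 10 for nuo-6 against WT (median -3.17), and 6 of 10 were higher and 2 lower on H3.3 loss in nuo-6.

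Some genes were near absent in some pools and abundant in others. In the order WT, his-72;his-71, daf-2, daf-2;his-72;his-71, nuo-6 and nuo-6;his-72;his-71, F56A4.3 had 19, 0.0668, 433, 0.0129, 0.251 and 0.0910 FPKM. F22B3.7 had 48.7 and 52.3 FPKM in the nuo-6 pools with and without H3.3, 1.0 in WT and between 0.0575 and 0.853 in the other pools. ZK218.5 had 34.8, 30.6, 0.264, 4.71, 0.0421 and 0.252, and F13G11.3 7.34, 0.0716, 0.0892, 45.3, 91.9 and 0.134. Near his-71, F45E1.4 was 2.77-fold and 2.82-fold lower on H3.3 loss in WT and daf-2 and 1.21-fold lower in nuo-6, but it shares its listed locus with sdpn-1 and its values are uncertain. R151.2 was listed at 0 in all 3 pools that lack his-71 and his-72 and had 197, 366 and 110 FPKM in WT, daf-2 and nuo-6, but cct-4, fat-4, rps-3 and other abundant genes were also listed at 0 in single pools or pairs of pools, so a listed 0 is not read as absence of the transcript.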
